A study of Mus musculus with 3 samples.

How the data were processed

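The series holds RNA-seq of 3 mouse (Mus musculus) pancreatic tumour cell lines, 1 library each. Per the labels, the lines came from tumours of transgenic mice with a p16-/- genotype and stand for a localized, an invasive and a metastatic stage of a progression model named HI-Panc. Cells were grown in DMEM with 10% fetal bovine serum, RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit from 1 ug of total RNA. The treatment text, which is the same for all 3 samples, describes 24 h of cobalt chloride at 100 ng/ml for hypoxic models. It does not say whether these 3 libraries came from treated cells, and no library labelled as an untreated partner was analysed here. The tissue label reads body wall for the localized line, pancreatic tissue for the invasive line and liver for the metastatic line. Groups were taken from the stage label.

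The values are FPKM per gene, deposited by the authors as 1 table with a column per library; the unit is stated per the file headers. The submitters' processing notes name STAR 2.5.2a, FastQC 0.11.2, Cufflinks 2.2.1 and the GRCm38 genome build, without giving the role or order of each tool. Whether reads were paired or stranded is not given in the sources used here, so overlapping and antisense genes cannot be told apart from their partners. The lowest deposited value was exactly 0.1 in each column, and 18, 6 and 8 values of the localized, invasive and metastatic columns lay within 1e-06 above it. The deposited FPKM was therefore read as FPKM with 0.1 added, and 0.1 was subtracted before every computation below. Of 22784 table entries, 27 carried a spreadsheet date number in place of a gene symbol, with 2 of these numbers repeated. These entries were left out because their genes cannot be named, which left 22757 genes. A further 20 genes of short RNAs and ribosomal RNA were left out of the counts by name. No mitochondrially encoded gene was among the genes analysed here.

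Differences between libraries were computed in log2(FPKM + 1), which understates the fold of genes with low values. A gene entered the counts with a mean of at least 1 FPKM over the 3 libraries (11404 genes, of which 615 had predicted-gene or clone names). It was called higher or lower where the difference was at least 1 on the log2 scale (2-fold). For the ordered stages, a gene had to differ by at least 0.585 (1.5-fold) in the same direction at both steps. With 1 library per group (n = 1) there are no replicates, so no difference has a replicate check and no p-value was computed. Counts compare these libraries and not the stages in general.

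For each of 48 gene lists (1013 symbols, of which 992 were among the genes of the table) the median difference over members past the filter was set against 10000 random lists of the same size. The random lists were matched on mean expression in 20 bins. Some genes are on several lists, so results of different lists are not independent. A list was said to stand apart where its median lay at or above the 97.5 percentile or at or below the 2.5 percentile, bounds outside which about 5% of random lists fall. Lists with fewer than 5 members past the filter were not assessed this way, which left 39. Of these, 25 stood apart for invasive against localized, 25 for metastatic against localized and 19 for metastatic against invasive. A share of 5% would be 1.95 lists. Random lists do not keep together genes that vary together, so standing apart was common and is not a 5% event for a given list. The lists, the rules of size, the rule for named genes and the alternative settings were fixed before the data were examined. The rule for named genes took the 8 largest differences in each direction for each pair of libraries and for the ordered stages, without predicted genes and pseudogenes. It also took up to 4 members with the largest difference from each list that stood apart or had at least 3 members past 2-fold. Isx, which the series title names, Cdkn2a and sex-linked genes were named in every case. The text names part of the genes the rule allows, and 1 gene that it names in every case is not reported here. Genes outside the rule are marked as chosen after their values were seen, with exceptions. These are Cdkn2b and Mtap beside Cdkn2a, Trp53, Smad4 and some members given to describe a list, such as the highest marker of a cell type. Where comparisons share the localized library, overlaps were set beside 100 shuffles of each gene's 3 values, a simulation of unchanged libraries and the overlap of independent lists.

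The table gives no counts. In genes with low values, however, the ratio between libraries fell within 0.02 (log2) of a ratio of whole numbers for 85.0% to 87.2% of genes, against 20.3% for evenly spread ratios. Steps of whole fragments were used with transcript lengths of the GENCODE M21 annotation of GRCm38 to estimate a depth of 42600000 fragments for the localized, 38600000 for the invasive and 40500000 for the metastatic library. Intervals on ratios are exact binomial 95% intervals of the estimated fragments. A gene at 0 was bounded at 3 fragments in that library. Both cover counting error only, because PCR copies are not independent molecules, and they leave out the spread between cultures. Gene positions, GC content and length came from the same annotation.

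Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counting rule was tested on simulated data for the metastatic against the localized library with 11403 genes. It recovered 94.0% of genes set 2.5-fold higher and 100% of those set 4-fold higher. Of genes set to 0.4 and 0.25 of their level it recovered 74.0% and 96.0%, and it called 0 unchanged genes. The simulated libraries shared the same mean profile and held only counting noise and a small random spread, not the spread between cultures. These values therefore test the computation and give no rate of false calls for the real libraries. A planted list of 20 genes reached percentile 100, and 4.00% of 200 random lists stood apart. Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, 3 other scalings (median of ratios, upper quartile, a common sum of 1000000), short RNAs kept, predicted genes left out, a 4-fold rule, means in place of list medians and 10 expression bins. The deposited values with the 0.1 kept, a correction for GC content and length, and the homeobox list without Isx were added to these after the data were seen. The planned summing of entries that share a symbol was not run, because no symbol was shared once the date numbers were left out.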

Results

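RNA-seq profiles of 3 mouse pancreatic tumour cell lines were compared, 1 library each from the localized, invasive and metastatic stages of the HI-Panc model. The series was laid out to follow gene expression along these stages in lines of the same engineered background, with the homeobox gene Isx as the gene of interest. The 3 libraries summed to 572661, 575446 and 565287 FPKM in the order localized, invasive, metastatic, and 11222, 11167 and 11115 genes reached 1 FPKM. Estimated depths were 42600000, 38600000 and 40500000 fragments. The 10 most abundant genes held 7.67%, 6.62% and 6.73% of the summed FPKM. None of the differences below has a replicate check, since each stage has 1 library.

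Isx, an intestine-restricted homeobox transcription factor (ENSMUSG00000031621.9, GRCm38 chromosome 8, 74873173 to 74893506, plus strand), was near the detection limit in the localized library and highest in the metastatic library. Its values were 0.041 FPKM in the localized library, which corresponds to about 3 fragments, 11.7 in the invasive library and 79.5 in the metastatic library. The metastatic over invasive ratio was 6.77 (95% counting interval 6.29 to 7.30). Against the localized library the ratios were 289 (98.4 to 1403) for the invasive and 1955 (669 to 9483) for the metastatic library. On the log2(FPKM + 1) scale these differences were 2.66, 3.61 and 6.27, and those against the localized library depend on the pseudocount, reaching 6.40 and 9.14 with 0.1. Cdx2, a homeobox factor of intestinal identity, followed the same order with 5.40, 35.2 and 70.6 FPKM, whereas its relative Cdx1 (chosen after its values were seen) was listed at 0 in all 3 libraries.

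The p16 gene of the genotype label was measured as a whole gene, so its values do not test the engineered allele itself. Cdkn2a (GRCm38 chromosome 4, 89274471 to 89294653, minus strand), whose transcripts encode p16Ink4a and p19Arf, was at 0 in the localized library and had 15.4 and 23.6 FPKM in the invasive and metastatic libraries. Against a floor of 3 fragments in the localized library it was at least 196-fold higher in the invasive and at least 300.5-fold higher in the metastatic library. Its neighbour Cdkn2b was at 0 in all 3, and Mtap on the other side had 67.9, 131 and 146 FPKM. The tumour suppressors Trp53 (123, 129 and 115 FPKM) and Smad4 (31.2, 38.7 and 36.4 FPKM) differed by less than 2-fold between any pair. X-linked Xist had 62.3, 39.6 and 39.9 FPKM, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0 in every library, as was X-linked Tsix. The other X-linked genes of the list differed by less than 2-fold between any pair, with 109.8, 103 and 116 FPKM for Eif2s3x, 121, 128 and 113 FPKM for Ddx3x, 12.2, 19.5 and 21.3 FPKM for Kdm5c and 10.02, 14.1 and 10.5 FPKM for Kdm6a.

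**Figure D1:**
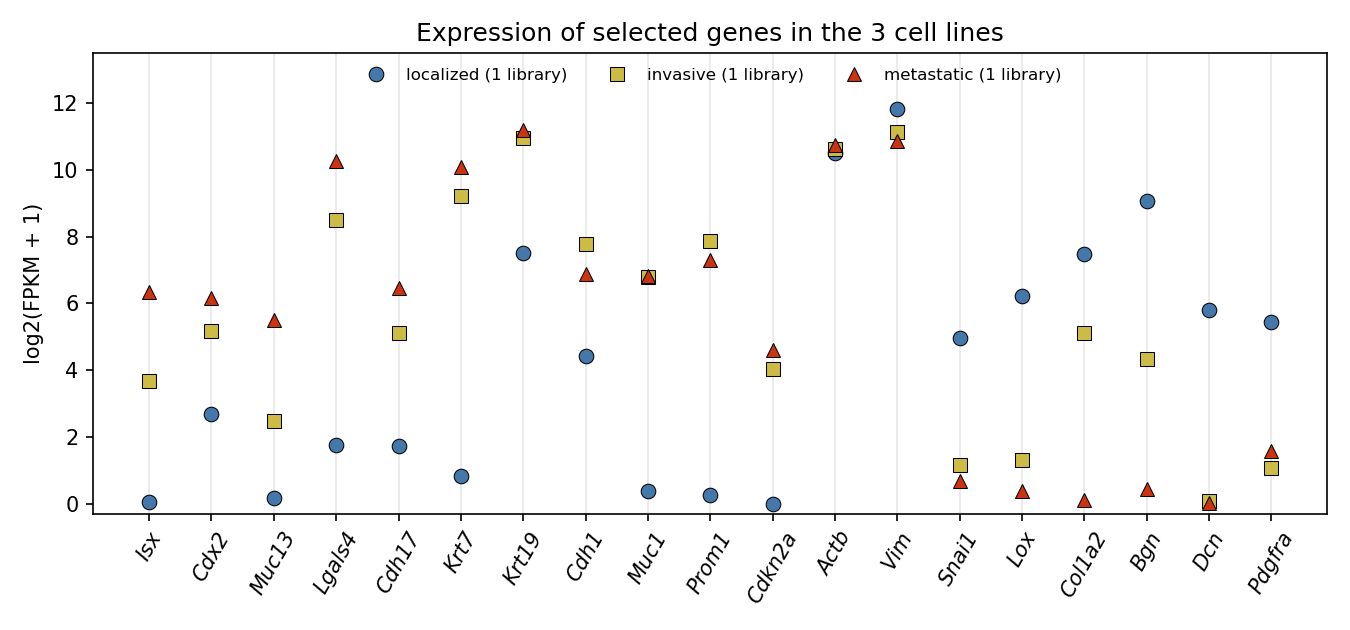
Expression of 19 genes in log2(FPKM + 1), 1 point per library (circles localized, squares invasive, triangles metastatic). Isx lies at 0.041 FPKM in the localized, 11.7 in the invasive and 79.5 in the metastatic library, while Bgn runs the other way from 535 to 19.097 and 0.354 FPKM; genes outside the naming rule were picked as familiar markers after their values were seen.

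The localized library stood apart from the other 2. Across 11404 genes the Spearman correlation was 0.975 between the metastatic and invasive libraries, 0.869 between the invasive and localized and 0.849 between the metastatic and localized libraries, with genes not being independent replicates. The SD of the log2 differences was 0.41 for metastatic against invasive, 0.94 for invasive against localized and 1.02 for metastatic against localized. In the closest pair 91.1% of genes lay within 1.5-fold, against 72.9% and 69.98% in the other pairs. Housekeeping genes had median differences of 0.03, 0.08 and 0.02 for invasive against localized, metastatic against localized and metastatic against invasive, inside the range of random lists. Ribosomal protein genes had -0.17, -0.23 and -0.09 in the same order. The second of these stood apart as lower (percentile 0.545), with 0 of 33 members past 2-fold. Immediate early genes, also listed as a quality check, differed as given below.

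**Figure D2:**
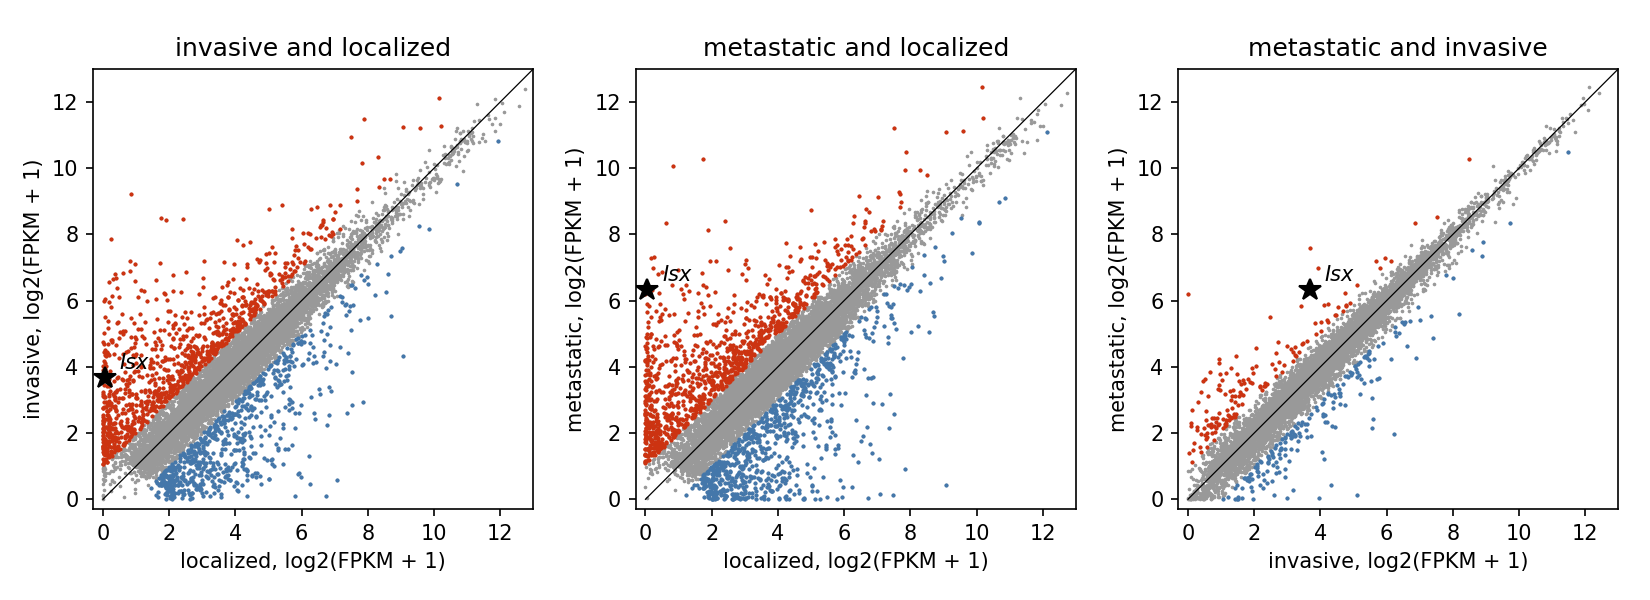
Each point is a gene past the filter, plotted by log2(FPKM + 1) in 2 libraries, with genes at least 2-fold higher in red and at least 2-fold lower in blue; the star marks Isx. The metastatic and invasive libraries lie close to the diagonal (152 genes higher and 191 lower), and both spread widely against the localized library.

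The comparison of the invasive with the localized library addressed, with the stages as labelled, the step from local to invasive growth. The tissue labels read body wall for the localized and pancreatic tissue for the invasive line, the reverse of what these stages would lead a reader to expect. If the lines were exchanged, every direction in this comparison would be reversed, and the 2 comparisons with the metastatic library given below would change places. Genes of epithelial, ductal and intestinal identity were higher in the invasive library, and genes of collagen, fibroblast and interferon programmes were lower. In all, 1001 genes were at least 2-fold higher (8.78% of those counted) and 692 at least 2-fold lower (6.07%). The largest difference was in Krt7, a keratin of ductal epithelium, with 0.793 FPKM in the localized and 598 FPKM in the invasive library. Prom1, a membrane glycoprotein known as CD133, had 0.191 and 234 FPKM, and the cell-surface mucin Muc1 had 0.297 and 111 FPKM. The intestinal lectin Lgals4 had 2.36 and 359 FPKM. The superoxide-producing oxidase Nox1 (2.73 and 343 FPKM), the oxidase maturation factor Duoxa2 (0.139 and 94.0 FPKM), the granulocyte colony-stimulating factor Csf3 (0.757 and 147 FPKM) and the growth factor Igf2 (0.235 and 101 FPKM) completed the 8 largest. In the other direction, the interleukin-33 receptor Il1rl1 had 105 FPKM in the localized and 0.061 in the invasive library. The retinoic acid-binding protein Crabp1 (134 and 0.507 FPKM), the fibroblast growth factor Fgf7 (75.9 and 0.379 FPKM) and the proteoglycan decorin, Dcn (54.4 and 0.071 FPKM), followed. Extracellular superoxide dismutase Sod3, the transcription factor Osr1, the Wnt antagonist Dkk2 and matrix Gla protein Mgp had 61.8, 59.8, 58.1 and 229.8 FPKM in the localized library and 0.598, 0.728, 0.701 and 6.66 FPKM in the invasive library.

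Of 18 epithelial genes past the filter, 15 were at least 2-fold higher in the invasive library and 0 lower, with a median difference of 2.59 (percentile 100 of random lists). Of the 30 listed, 20 reached 1 FPKM in the invasive and 8 in the localized library. The tight-junction protein Tjp3 had 0.367 FPKM in the localized and 39.98 FPKM in the invasive library, the lipoprotein receptor Lsr 0.201 and 26.0 FPKM and desmoplakin, Dsp, 0.111 and 19.9 FPKM. Ductal markers had a median difference of 2.46, with 6 of 11 members higher, among them carbonic anhydrase Car2 (0.584 and 32.9 FPKM) and the tetraspanin Tspan8 (31.2 and 439 FPKM). Intestinal genes had a median of 2.40 with 7 of 12 higher, including Anxa13 (0.041 and 44.5 FPKM), and 1 lower, the goblet-cell peptide Tff3 (31.5 and 0.524 FPKM). Isx is itself on this list and among the higher genes, and only 12 of the 26 listed genes passed the filter. Genes of gastric and classical pancreatic tumour identity had a median of 1.66 with 9 of 16 higher, such as the gastric claudin Cldn18 (0.345 and 82.8 FPKM). Basal and squamous genes had a median of 1.06 with 5 of 9 higher, including the laminin chain Lamb3 (1.85 and 16.6 FPKM). All 5 lists stood apart. They share members, such as Krt7 and Krt19 in the epithelial and ductal lists and Lgals4 in the intestinal and gastric lists.

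Mesenchymal genes had a median difference of -1.17, with 10 of 18 at least 2-fold lower in the invasive library and 0 higher. The transcription factors Prrx1 (83.7 and 4.34 FPKM in the localized and invasive libraries) and Snai1 (30.2 and 1.26 FPKM), the collagen crosslinker Lox (74.0 and 1.49 FPKM) and the gelatinase Mmp2 (17.9 and 1.10 FPKM) had the largest differences. The other 8 members were within 2-fold. Among them, chosen after their values were seen, were Vim (3640 and 2231 FPKM), S100a4 (6019 and 3749 FPKM) and Zeb1 (12.9 and 13.1 FPKM). Collagens and other matrix genes had a median of -1.74, with 16 of 28 lower and 4 higher; the proteoglycan biglycan, Bgn, had 535 and 19.097 FPKM and Col6a3 44.0 and 1.87 FPKM. Fibroblast markers had a median of -2.63, with 11 of 13 lower, including the growth factor receptor Pdgfra (42.7 and 1.09 FPKM) and the chemokine Cxcl12 (19.3 and 0.064 FPKM). Each of these 3 lists lay at percentile 0 of random lists. They share members with one another, such as Prrx1 and Col1a1 in the fibroblast list. The localized library, in which epithelial, ductal and intestinal genes were lower, was thus the library with the higher fibroblast markers.

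Interferon-response genes were lower in the invasive library for 21 of 31 members and higher for 2, with a median of -1.37 at percentile 0. Ifit1 had 55.2 FPKM in the localized and 5.14 in the invasive library, Ifit3 22.9 and 1.65 FPKM, and the ubiquitin-like modifier Isg15 218 and 41.7 FPKM. Antigen-presentation genes did not stand apart (median 0.12, percentile 83.7). Inflammatory cytokines went both ways, with 12 of 26 higher and 8 lower around a median of 0.76 (percentile 100). Csf2 had 0.948 and 96.2 FPKM and the chemokine Ccl20 3.35 and 108 FPKM in the localized and invasive libraries, whereas Ccl7 had 109 and 3.76 FPKM.

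Lipid synthesis genes were higher in the invasive library. Cholesterol synthesis genes had a median of 1.01, with 12 of 23 at least 2-fold higher and 0 lower, among them Fdps (31.9 and 107 FPKM) and the sterol sensor Insig1 (7.41 and 27.7 FPKM). Fatty acid synthesis genes had a median of 1.11, with 8 of 15 higher and 0 lower, including the desaturases Fads2 (9.67 and 47.5 FPKM) and Scd2 (95.8 and 309 FPKM). Immediate early genes had a median of 1.07 with 7 of 14 higher and 0 lower; Fos had 1.15 and 47.1 FPKM and Egr1 21.7 and 74.4 FPKM. All 3 lists lay at percentile 100. Proliferation genes had a median of -0.19 (percentile 0.690), but 0 of 33 members differed by 2-fold, the furthest being the centromeric histone Cenpa (97.4 and 58.7 FPKM).

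The comparison of the metastatic with the localized library, the ends of the series as labelled, gave 1035 genes at least 2-fold higher (9.08%) and 831 at least 2-fold lower (7.29%). Under an exchange of the localized and invasive lines these would be the counts for metastatic against invasive. Intestinal and epithelial genes were again the higher groups, and matrix, fibroblast and interferon genes the lower ones. Krt7 had 0.793 FPKM in the localized and 1077 in the metastatic library, Lgals4 2.36 and 1239 FPKM and the calcium-activated chloride channel regulator Clca4 0.531 and 327 FPKM. Tmigd1 (0.129 and 156 FPKM), the interleukin-5 receptor chain Il5ra (0.175 and 126 FPKM), the transmembrane protease Tmprss2 (0.403 and 116 FPKM), Prom1 (0.191 and 157 FPKM) and Muc1 (0.297 and 112 FPKM) were the other 5 largest. Bgn had 535 FPKM in the localized and 0.354 in the metastatic library, and the type I collagen chain Col1a2 had 177 and 0.083 FPKM. Mgp (229.8 and 0.877 FPKM), Crabp1 (134 and 0.111 FPKM), Il1rl1 (105 and 0.037 FPKM), Osr1 (59.8 and 0.038 FPKM), Lox (74.0 and 0.305 FPKM) and the pigment epithelium-derived factor Serpinf1 (131 and 1.33 FPKM) were also far lower.

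Intestinal genes had the largest positive list median in this comparison, 3.21, with 10 of 12, Isx among them, at least 2-fold higher and 1, Tff3, lower. Epithelial genes had a median of 2.28, with 17 of 18 higher and 1 lower, and the junction protein occludin, Ocln, was at 0 in the localized and at 17.6 FPKM in the metastatic library. Ductal markers (2.13), gastric and classical genes (1.49), basal and squamous genes (1.13), fatty acid synthesis genes (0.85) and cholesterol synthesis genes (0.79) also stood apart as higher. Tff1, a gastric trefoil peptide, went against its list with 101 and 3.55 FPKM. Fibroblast markers had a median of -3.88 with 11 of 13 lower and 1 higher. Collagen and matrix genes had -1.95 (16 of 28 lower), interferon-response genes -1.78 (26 of 31 lower) and mesenchymal genes -1.43 (11 of 18 lower, 0 higher). Antigen-presentation genes stood apart as lower, with a median of -0.31 (percentile 0.720) and 5 of 17 lower, among them beta-2-microglobulin, B2m (1868 and 546 FPKM), and the immunoproteasome subunit Psmb8 (31.2 and 10.3 FPKM). Inflammatory cytokines had 8 members higher and 8 lower of 26. Their median of 0.38 stood apart, but their mean of 0.04 did not, nor did their median without the filter on low values (0.05). Proliferation genes had a median of -0.35 (percentile 0), with only E2f1 of 33 members at least 2-fold lower (33.0 and 15.9 FPKM).

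Because both comparisons above use the same localized library, part of their overlap arises without any effect. The invasive and metastatic libraries differed from the localized library in the same direction for 83.3% of genes, against 66.7% in simulated unchanged libraries and 66.6% after shuffling. The simulation gave every library the spread seen between the metastatic and invasive libraries. The correlation of the differences across genes was 0.916, against 0.50 in the simulation, and their covariance was 0.877, against 0.083. Both values follow from the SDs of the differences given above, so they restate that the localized library stood apart and add no separate evidence. Genes at least 2-fold higher in both numbered 812, where shuffling each gene's values gave 314 and independent lists would share 90.8. Genes lower in both numbered 597, against 262 after shuffling and 50.4 for independent lists. Only 3 genes were past 2-fold in opposite directions. The single localized library could not be split, so part or all of the excess may come from that shared library standing apart.

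**Figure D3:**
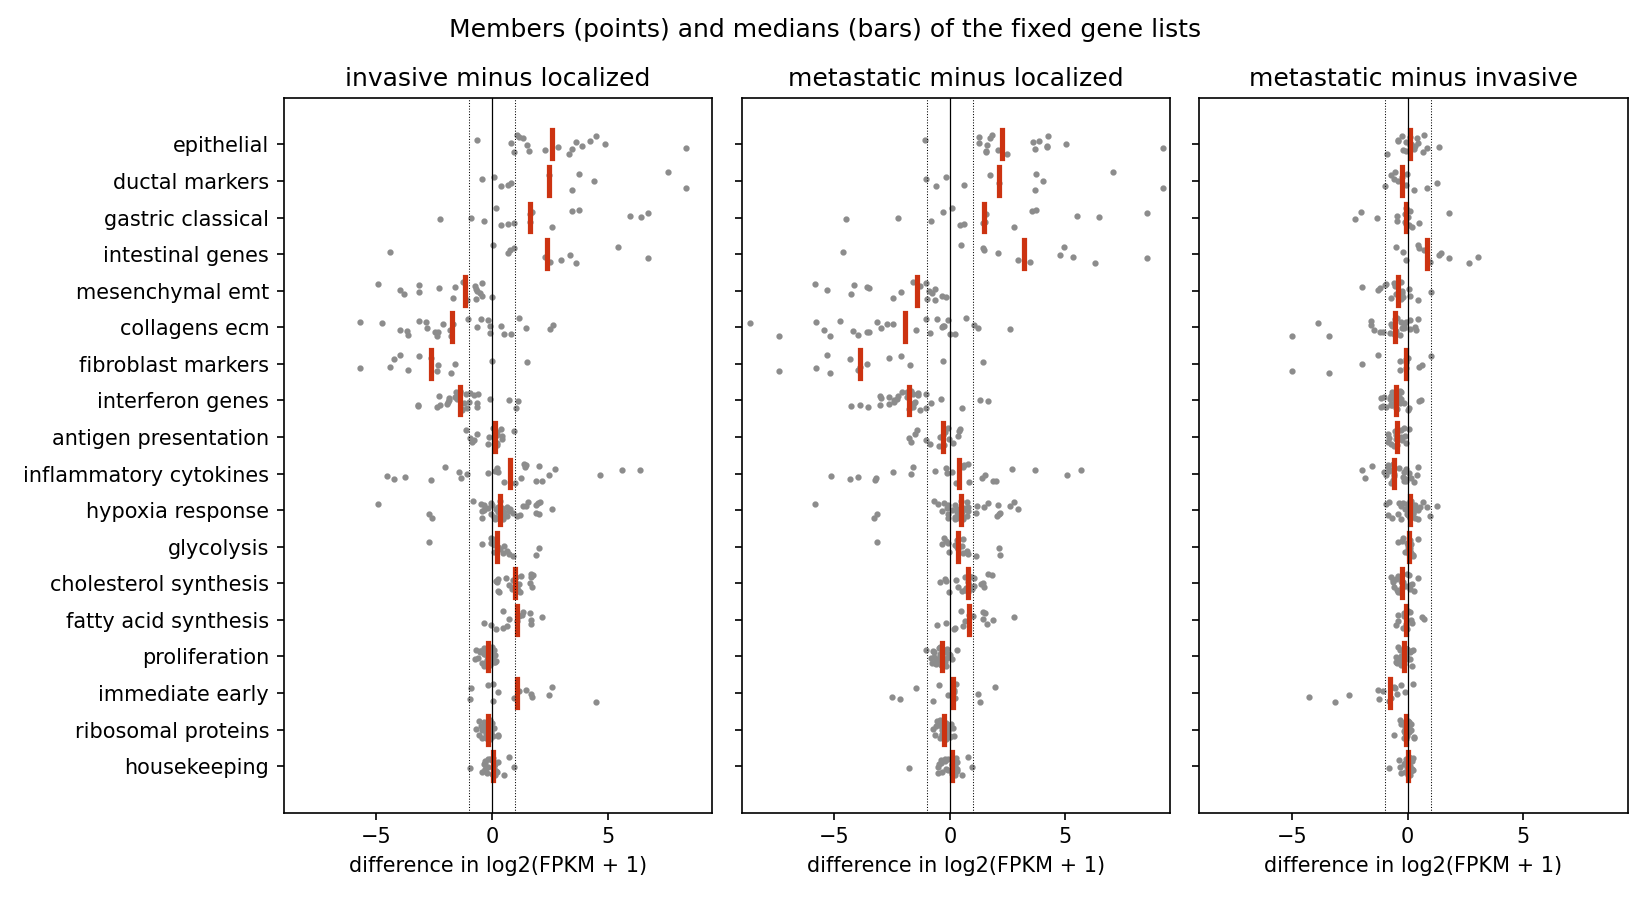
Differences in log2(FPKM + 1) for members of 18 gene lists (grey points) with list medians (red bars), for the 3 pairs of libraries; dotted lines mark 2-fold. Epithelial, ductal and intestinal medians lie above 2 against the localized library, whereas against the invasive library the intestinal median of 0.85 is the furthest on the positive side.

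The metastatic and invasive libraries were the most alike, with 152 genes at least 2-fold higher in the metastatic library (1.33%) and 191 lower (1.67%). Under the same exchange the closest pair would be the metastatic and localized libraries. Intestinal genes were higher in the metastatic library, while immediate early, cytokine and collagen genes were lower. The 12 intestinal genes had a median difference of 0.85 (percentile 100), with 5 at least 2-fold higher and 0 lower. Isx is 1 of the 5, and the median was not recomputed without it. Muc13, a transmembrane mucin of the gut, had 4.59 FPKM in the invasive and 44.7 in the metastatic library, Lgals4 359 and 1239 FPKM and the glycoprotein Gpa33 0.722 and 3.61 FPKM. Without the filter on low values the median of this list was 0.01 and it no longer stood apart. The desmosomal cadherin Dsc2 (0.904 and 17.9 FPKM), the claudin Cldn6 (0.914 and 16.5 FPKM), the peptide hormone Cck (0.569 and 13.2 FPKM), Acsm3 (1.72 and 19.13 FPKM) and Mgat4c (0.325 and 8.45 FPKM) were among the largest differences. The small proline-rich genes Sprr2b (0.420 and 11.5 FPKM) and Sprr2h (14.3 and 125 FPKM) were as well, although they belong to a family of similar genes between which reads are hard to assign.

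Genes lower in the metastatic than the invasive library included both type I collagen chains, Col1a2 (33.4 FPKM in the invasive and 0.083 in the metastatic library) and Col1a1 (46.3 and 3.45 FPKM), and Bgn (19.097 and 0.354 FPKM). The homeobox factor Pitx1 had 14.4 and 0.030 FPKM and the keratin Krt23 7.97 and 0.220 FPKM. Eif3j1 had 6.88 and 0.035 FPKM but has a near-identical copy, Eif3j2, so its level is uncertain. Collagen and matrix genes had a median of -0.53 with 8 of 28 lower and 0 higher. Immediate early genes had a median of -0.76 with 6 of 14 lower and 0 higher, including Egr1 (74.4 and 2.96 FPKM), Fos (47.1 and 4.39 FPKM) and Ier2 (167 and 28.0 FPKM). Inflammatory cytokines had a median of -0.60 with 4 of 26 lower, such as Csf2 (96.2 and 23.6 FPKM) and Ccl2 (162 and 45.0 FPKM). Interferon-response genes (-0.52, 4 of 31 lower), antigen-presentation genes (-0.44, 0 of 17 past 2-fold), mesenchymal genes (-0.40, 3 of 18 lower and 1 higher) and genes of TGF-beta signalling (-0.36, 3 of 22 lower, among them Ctgf with 91.9 and 37.8 FPKM) lay at percentile 0 as well. Fibroblast markers did not stand apart by their median of -0.08 (percentile 20.6), though they did as lower by their mean of -0.80, with a pseudocount of 0.1 (median -0.39) and with a mean of at least 5 FPKM (median -0.32). Epithelial genes had a median of 0.12 just inside the range of random lists (percentile 97.3), and passed the bound under the median-of-ratios scaling (0.12), with the deposited 0.1 kept (0.12) and after the GC and length correction (0.13).

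Along the ordered stages, 168 genes were at least 1.5-fold higher at both steps and 176 lower at both steps. Shuffling the 3 values of each gene gave medians of 88 and 89 over 100 shuffles, with highest counts of 110 and 113. That shuffle makes all orders equally likely, and because the localized library stood apart from the other 2, an excess over it does not show a stepwise progression. By the same 1.5-fold rule, 125 genes ran upward from localized through metastatic to invasive and 48 downward. With the localized library in the middle, as an exchange of the localized and invasive lines would place it, 7 genes did in each direction. The order from localized through invasive to metastatic held for 2583 genes increasing (22.7%) and 2767 decreasing (24.3%), where 6 equally likely orders would hold 16.7% each. The other orders with the localized library at an end were also above that share, with 2182 genes (19.13%) lowest in the localized and highest in the invasive library and 1972 (17.3%) the reverse. The 2 orders with the localized library in the middle held 983 (8.62%) and 917 genes (8.04%). These counts take the stages as labelled. With the localized and invasive lines exchanged, Isx would run from 11.7 through 0.041 to 79.5 FPKM, with no stepwise increase. Isx was among the 8 genes with the largest stepwise increase, together with Krt7, Lgals4, Clca4, Tmigd1, Il5ra, Tmprss2 and the mast cell protease gene Mcpt2. Mcpt2 was at 0 in the localized library and had 25.7 and 74.6 FPKM in the invasive and metastatic libraries. The largest stepwise decreases were in Bgn, Col1a2, Mgp, Osr1, Lox and Serpinf1, given above, and in the kinase Sgk1 (113, 4.80 and 1.62 FPKM) and Col6a3 (44.0, 1.87 and 0.047 FPKM).

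Cobalt chloride stabilises hypoxia-inducible factors, and genes of the hypoxia response were therefore examined. Their median was 0.36 for invasive against localized, 0.47 for metastatic against localized and 0.11 for metastatic against invasive, and all 3 stood apart. In the first of these the mean of 0.33 did not. In both comparisons with the localized library 11 of 42 members were at least 2-fold higher and 3 lower. The prolyl hydroxylase Egln3 had 24.2, 152 and 195 FPKM in the localized, invasive and metastatic libraries, and hexokinase Hk2 had 15.9, 63.2 and 74.2 FPKM. Carbonic anhydrase Car9, a classical hypoxia target, ran the other way with 48.1, 7.23 and 4.15 FPKM, as did the enolase Eno2 with 10.2, 0.692 and 0.272 FPKM. Glycolysis genes had medians of 0.22 and 0.35 against the localized library, which stood apart, while their means of 0.29 and 0.33 did not. All glycolysis genes but Pfkm and Pkm are also on the hypoxia list, so these results are not independent of it. Metal and oxidative stress genes had medians of -0.21, -0.23 and 0.18 in the 3 comparisons. All 3 stood apart, but the first no longer did after a correction for GC content and length, and the mean of the second, -0.15, did not. The quinone reductase Nqo1 (182, 13.4 and 38.7 FPKM) and heme oxygenase Hmox1 (84.9, 16.8 and 20.9 FPKM) were highest in the localized library. Whether any library came from treated cells is not stated, so these values describe the lines and not a response to cobalt.

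Most acinar, islet and hepatocyte markers were low, while single markers of other cell types were high. Of 23 acinar markers, 1 reached 1 FPKM in the localized library, Cela1 with 7.24 FPKM, and 0 did in the metastatic library. The highest islet marker was Pax6 with 2.59 FPKM in the localized library. In the metastatic line, labelled as derived from liver, 0 of 25 hepatocyte markers reached 1 FPKM, the highest being Apoa2 with 0.606 FPKM. Endothelial markers were led by Flt1 with 23.1, 17.6 and 9.20 FPKM, and melanocyte markers did not exceed 1.42 FPKM (Mitf, localized library). Among muscle markers the highest was Tnni2 with 3.09 FPKM in the invasive library. Of 11 mesothelial markers, 2 passed the filter, Msln (106, 291 and 409 FPKM) and Krt19 (181, 1970.2 and 2365 FPKM), the second also an epithelial and ductal marker. Of 29 leukocyte markers, 3 reached 1 FPKM in the localized, 5 in the invasive and 4 in the metastatic library. Ptprc (chosen after its values were seen) had 0.017, 0.197 and 0.069 FPKM. Only 5 members passed the filter, with medians of 1.20 and 0.91 against the localized library. Among these, Cd14 had 84.8, 139 and 80.3 FPKM, Cd68 4.82, 10.5 and 9.93 FPKM and Mrc1 1.90, 8.36 and 7.03 FPKM. Neither leukocyte value stood apart without the filter on low values. The second also did not with a pseudocount of 0.1 (median 1.03) or by its mean (0.95). Neural markers, also with 5 members past the filter, had medians of -1.15 and -1.76 against the localized library and -0.61 for metastatic against invasive. All 3 stood apart as lower, but none did without the filter, and the mean of the first, -0.72, did not. Tubb3 had 46.3, 11.2 and 2.67 FPKM and Stmn2 18.1, 1.67 and 0.013 FPKM. The placental prolactin-family genes Prl2c2 (565, 491 and 481 FPKM) and Prl2c3 (321, 328 and 329.9 FPKM), which are close copies, were high in all 3 libraries.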

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

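Both results below were singled out because a signal appeared in values that no comparison in the report uses. No tests were run on either of them after they were seen, and no biological explanation was tested.

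Of the 27 entries that carry a date number in place of a gene symbol, 16 had a mean of at least 1 FPKM and would have entered the counts under a proper name. In these 16, 2 were at least 2-fold higher and 1 lower in the invasive than the localized library, 1 was higher and 1 lower in the metastatic than the localized library, and 0 were past 2-fold between the metastatic and invasive libraries. Their genes cannot be named from the number alone, so the counts of genes in the report leave these entries out.

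Rn45s, the 45S ribosomal RNA precursor, was left out by name and had 350.5 FPKM in the localized library, against 199 FPKM in the invasive and 273 FPKM in the metastatic library. Keeping Rn45s and the other short RNA genes moved the count of genes lower in the invasive than the localized library from 692 to 693 and left the other 7 counts as they were.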

How the results depend on the processing

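The alternatives with the 0.1 kept, with GC content and length corrected and with Isx left out of the homeobox list were chosen after the data were seen; the others were planned. Among recomputed counts of genes and of lists, SDs and overlaps, 117 stayed within 1.5 times the main count or near the main value and 25 moved. Under the 3 other scalings every count of genes stayed within 1.5 times the main count, and the median difference of all genes stayed within 0.043 of 0. Moved values mostly follow from how a setting is built. The 4-fold rule gave 360 genes higher and 252 lower for invasive against localized, 393 and 314 for metastatic against localized, 33 and 22 for metastatic against invasive, and 47 and 53 along the stages with 2-fold steps. A mean of at least 5 FPKM, which counts fewer genes, gave 376 and 488 genes lower than localized in the invasive and metastatic libraries, 69 higher in metastatic than invasive, 108 higher at each stage and an SD of 0.376 for metastatic against invasive. A pseudocount of 0.1, which widens differences of low genes, gave 373 genes lower in metastatic than invasive, 317 lower at each stage and SDs of 1.25, 1.39 and 0.547 for invasive and metastatic against localized and metastatic against invasive. With 0.5 these SDs were 1.05, 1.15 and 0.457. Without a filter they were 0.685, 0.743 and 0.305, and 61.9% of genes, many of them at 0, shared a direction from the localized library.

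Isx kept its order in each setting. Its differences from the localized library in the invasive and metastatic libraries were 6.40 and 9.14 with a pseudocount of 0.1, 4.50 and 7.21 with 0.5, and 4.32 and 7.05 scaled to a sum of 1000000, because the localized level lies near 0. Of the recomputed list medians and means, 1209 kept their call, 35 gained one, 35 lost one and 2 that stood apart in the main setting changed sign. These 2 were in retinoid genes for metastatic against localized, at 0.0004 without the filter and 0.0702 at a sum of 1000000, where more members entered. The cause was not tested further. Some that gained a call also changed sign with the mean in place of the median. Imprinted genes went from -0.39 to 0.82 for invasive against localized. Stem-like genes went from -0.19 to 0.68 for metastatic against localized, and retinoid genes from 0.05 to -0.38 for metastatic against invasive. No paired analysis was possible because each group has 1 library. Depth limits genes near 0: 3 fragments correspond to 0.039 FPKM for Isx in the localized library.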

Other observations

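The tests on the localized profile and on the Cdkn2a locus were chosen only after those results were seen, while the tests on chromosomes were written down beforehand. Of the signalling and adhesion lists here, Notch and Hedgehog genes stood apart in both comparisons with the localized library. They had a median difference of 1.33 for invasive against localized (6 of 9 at least 2-fold higher, 1 lower) and 1.03 for metastatic against localized, the second of which did not stand apart without the filter on low values. For metastatic against invasive they stood apart as lower (median -0.29, percentile 0.625, 0 of 9 past 2-fold), though not by their mean of -0.29. The Notch ligand Dll1 had 0.148, 13.7 and 9.41 FPKM in the localized, invasive and metastatic libraries, and the target Hes1 9.11, 66.9 and 40.8 FPKM, while the Hedgehog effector Gli3 had 5.83, 0.705 and 0.660 FPKM. Wnt pathway genes went both ways, with 6 of 19 higher and 6 lower in the invasive than the localized library, and did not stand apart (percentiles 96.1 and 84.0), although with a mean of at least 5 FPKM both medians did (0.72 and 0.57), and the first also did with a pseudocount of 0.1 (0.31) or without the filter (0.10). Wnt7b had 1.36, 78.0 and 87.1 FPKM, whereas Wnt10b had 13.2, 0.864 and 0.673 FPKM. Receptor kinases and ligands did not stand apart either (8 of 24 higher and 5 lower), with Igf2 among the higher and Fgfr1 (42.7, 3.79 and 2.09 FPKM) and Ddr2 (35.0, 1.02 and 0.184 FPKM) among the lower. Integrins and adhesion genes stood apart as higher in the invasive library (median 0.32, 9 of 21 higher), led by Ceacam1 (0.129, 19.7 and 30.9 FPKM) and Itga2 (2.84, 64.1 and 56.3 FPKM), although not without the filter on low values. For metastatic against localized the median was -0.18 (percentile 4.09), and it stood apart as lower without the filter (-0.22), with a mean of at least 5 FPKM (-0.21) and after the GC and length correction (-0.24). For metastatic against invasive it was -0.24 (percentile 0.060) and stood apart as lower, with 0 of 21 at least 2-fold higher and 1 lower.

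Homeobox genes did not follow Isx as a group. The list, Isx included, had a median of -0.42 for invasive and -0.48 for metastatic against localized, and without Isx, a setting chosen after the data were seen, -0.50 and -0.49. Both calls for the list with Isx were lost without the filter on low values or with the mean in place of the median, and the first also with a mean of at least 5 FPKM. Hoxa13 had 0, 0.086 and 5.46 FPKM in the localized, invasive and metastatic libraries, Hoxa5 3.32, 0.10 and 1.81 FPKM, and Pitx1 was high in the invasive library alone with 14.4 FPKM against 0.039 and 0.030. In the retinoid group, Stra6 (0.101, 34.8 and 12.6 FPKM) and Aldh1a3 (2.58, 74.4 and 84.0 FPKM) ran opposite to Crabp1 and to Crabp2 (17.8, 1.92 and 2.39 FPKM). Matrix proteases did not stand apart in any pair by their median, though their mean of -0.42 for metastatic against localized did, with Timp3 at 165, 5.07 and 8.15 FPKM and the cathepsin Ctsh at 15.5, 228 and 133 FPKM. The G1 cyclin Ccnd2 had 7.30, 47.5 and 60.5 FPKM and the inhibitor Cdkn2c 72.7, 17.8 and 18.7 FPKM. For metastatic against invasive, p53 targets had a median of 0.35 (percentile 100), although 0 of 20 were at least 2-fold higher and the 1 past 2-fold, Gadd45a, was lower, with 20.2 FPKM in the invasive and 8.10 in the metastatic library. Imprinted genes had a median of 1.33 for metastatic against localized over 7 members, with 4 at least 2-fold higher, led by Igf2 (0.235, 101 and 50.2 FPKM), and 1 lower, Dlk1 (5.38, 0.128 and 0.028 FPKM), and this was lost without the filter on low values.

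The localized library combined high matrix and fibroblast genes with low epithelial genes, and its label names the body wall as tissue. A mixture of cells like the invasive line with cells that lack epithelial genes would lower the epithelial genes by about the same factor, but over 12 epithelial genes at 10 FPKM or more in the invasive library the localized level ranged from 0% (Ocln) to 44.1% (Spint2) of the invasive level, and the upper quartile of 23.1% was 32.1 times the lower quartile of 0.720%, which argues against such a mixture as the whole account. A line of stromal cells in place of tumour epithelium stays open. In the localized library 6 of 30 epithelial genes reached 10 FPKM, too many for none and too few for most. The 6 ran from Cdh1 (20.7 FPKM) to Krt8 (765 FPKM). This count cannot decide the question, because the invasive library, with 12 genes at 10 FPKM or more, would also fall short of most. Genes of gastric and classical identity were as divided, with 12 of 25 at 1 FPKM or more in the localized library and a median of 0.552 FPKM, from Tff2 (482 FPKM) and Pdx1 (58.6 FPKM, chosen after its values were seen) to Cldn18 (0.345 FPKM) and Muc1 (0.297 FPKM). A difference in cell state between tumour lines, and an exchange of the localized and invasive labels, may also account for the profile and were not tested.

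Whole chromosomes differed by small amounts between the metastatic and invasive libraries, with medians of 0.26 on chromosome 5, -0.25 on 14, -0.16 on 9 and -0.17 on X. Against the localized library the invasive and metastatic medians were -0.20 and 0.09 on 5, 0.33 and 0.06 on 14, -0.07 and -0.22 on 9 and -0.01 and -0.23 on X, while the largest, -0.36 and -0.32 on 19, and the -0.24 and -0.25 on 4 were shared by both. Parts of chromosomes differed more. On chromosome 16 the running median over 51 neighbouring genes reached 0.853 for invasive and 1.065 for metastatic against localized. This region was picked after its values were seen, and no shuffles were run for such windows. Chance placement of genes is argued against, because the highest median in 10000 shuffles of gene positions was 0.069 between the metastatic and invasive libraries, where 7 chromosomes exceeded it, and 0.130 and 0.141 for invasive and metastatic against localized, where 5 did in each. GC content and transcript length are argued against for the 4 named first, because at least 98.3% of each median between the metastatic and invasive libraries remained after their trends were removed. A difference in DNA copy number could give such shifts and stays open, because DNA was not measured here and the share of genes on the side of the shift was 85.5%, 85.4% and 74.7% on chromosomes 5, 14 and 9 but 65.3% on X, where the median was -0.39 in the first part of the chromosome and 0.05 in the second.

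Cdkn2a was at 0 in the localized library and above 10 FPKM in the others. Depth is argued against, because the invasive level was 196 times the level that 3 fragments give in the localized library. A shared allele that removes all Cdkn2a signal in every line is argued against by the 23.6 FPKM of the metastatic library. Whole-gene values do not test the engineered allele itself. Loss of a segment reaching Mtap is argued against by 67.9 FPKM of Mtap in the localized library. A short deletion or silencing of the locus cannot be told apart here, since Cdkn2b was at 0 in all 3 libraries and the gene Dmrta1 beyond it (chosen after its values were seen) had 0.640 FPKM in the localized library; DNA would be needed to tell them apart. This locus may therefore be worth examining at the DNA level in the localized line.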
